A study of Cucumis sativus with 4 samples.

How the data were processed

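RNA was sequenced from roots and leaves of cucumber (Cucumis sativus) plants 28 days after sowing, fed either a complete solution with 5 mM nitrate or a low nitrogen solution with 1 mM nitrate. Per the labels' protocols, plants grew in pots of sand with 14 h of light per day, 0.1 g of tissue was taken per sample, and libraries were made from 6 µg of total RNA; the series' design text names the Illumina HiSeq 2000. The labels name 4 libraries, with 1 library in each of the groups root control, root low nitrogen, leaf control and leaf low nitrogen. The salts replacing nitrate made the solutions differ in other ions. By the recipes in the labels, sulfate was 0.25 mM in the control solution and 1.45 mM in the low nitrogen solution, and chloride was 0.2 and 1.8 mM. Phosphate (0.25 mM), potassium (4.25 mM) and calcium (0.5 mM) were the same in both.

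The authors deposited 1 table of RPKM values (reads per kilobase of gene per M reads, M for mega) for 18665 genes, with a gene length, a symbol and an Arabidopsis homologue ID per gene. Bowtie 0.12.9 is named in the submitters' processing notes; the genome build, the counting program and the reads that make up the M reads are not given in the sources used here. The table gives a scaffold but no position for each gene, so no coordinates are printed. A symbol was given for 7678 genes and a homologue ID for 17654; 4 symbols had been turned into dates. None of the gene IDs matched the RefSeq gene table, in which 0 of 23999 genes shared an ID with the deposited table, so symbols and homologues are those of the deposited table and were not checked further. A symbol names the Arabidopsis homologue, and 7819 genes shared their homologue with another cucumber gene; genes are printed with their symbol, homologue ID and, where several genes have the symbol, scaffold, and copies on 1 scaffold differ by their values. Copies of one family may share reads, because how reads matching several genes were counted is not given in the sources used here.

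The deposited RPKM values are not counts, and the ratios were made from them as they are; counts and depths recovered from them were used only for reads printed, intervals, floors, simulated data and 1 alternative. The depth was recovered from the steps between values: RPKM times the length in kilobases is a whole number of reads divided by the library's reads in M. With a tolerance of 0.00501 RPKM, 1291 of 5071 genes that could be checked were whole in every library at their deposited length, against 0 of 6740 genes after the values were shuffled. The reads behind the scaling came to 4.23 M for root control, 3.98 M for root low nitrogen, 2.93 M for leaf control and 2.74 M for leaf low nitrogen. The other genes were not whole at their deposited length, so the smallest whole read counts allowed by any length from 100 bases up to the deposited length were taken. Such counts existed for 82.4% of genes; why the rest had none was not settled, and they have no interval. Among genes with a mean of at least 1 RPKM the share was 81.2%, against 37.1% for shuffled values, so the counts of a single gene are not certain; the smallest ones give the widest intervals. Ratios of these counts have exact conditional (Clopper-Pearson) 95% intervals. A fold against a library at 0 is a lower bound against a floor of 3 reads in that library. Intervals and floors cover counting error only.

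Ratios were log2((A + 1)/(B + 1)) of the deposited RPKM, with a pseudocount of 1, which understates the ratios of genes with low values. A gene entered a comparison with a mean of at least 1 RPKM over the libraries compared, and counted as higher or lower at an absolute log2 ratio of at least 1. With 1 library per group no difference has a replicate check, and no p-value or standard error is given. The comparisons were low nitrogen against control in root and in leaf, leaf against root in each treatment, and the difference between the leaf and root log2 ratios.

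The genes named were set by rule, among genes with a mean of at least 5 RPKM: the 10 highest and 10 lowest genes with a symbol per tissue, the 5 highest and 5 lowest between tissues in the controls, the 5 at each end of the difference between tissues, all members of the nitrate transport, nitrate reduction, ammonium assimilation and ammonium transport lists, and up to 3 members with the largest ratio from each other list. Genes named outside this rule, as in the closing section, were chosen after their values were seen. The median log2 ratio of each list was placed among the medians of 10000 random lists of the same size, matched on 20 bins of mean expression. A list is said to stand apart at or below the 2.5th or at or above the 97.5th percentile; this describes these libraries and is not a p-value across plants. A list needed 5 measured members, except those on nitrogen.

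The groups, comparisons, thresholds, rule for naming genes, list themes and all but 2 of the processing alternatives were set before the data were examined. The 42 lists had been written as words to be matched to product descriptions. The deposited table has no descriptions, so each list was rewritten by hand as symbols and Arabidopsis IDs, with knowledge of which genes were in the table and before the expression of any member was examined. In this step the list on endodermis became one of root cell types, and that on leaf cuticle became one of leaf epidermis and polarity. A named gene was taken to be one with a symbol, since the rule had asked for a product name. Lists of low-oxygen, early leaf growth and clock genes were written later, after the main results had been seen.

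The alternatives were pseudocounts of 0.1 and 5; no filter on low values and a mean of at least 5 RPKM; scaling by the median ratio to the geometric mean, by the upper quartile, to equal sums, and to equal sums without the 20 highest genes; a counting interval excluding 1; and random lists not matched on expression. After the data had been seen, 2 were added: ratios minus the median over all genes, and genes with the same homologue summed.

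The steps were tested on simulated data made from the real genes' levels and the recovered depths, with 200 genes changed by known folds. Some simulated genes kept their deposited length, and most were given a shorter one drawn at random. The simulated counts, and so the shares below, depend on these drawn lengths. All 4 depths were recovered to within 0.000342%, and the true counts of 79.0% of 14963 genes were recovered exactly, with the smallest allowed total never above the true one. Allowed counts existed for 99.96% of these simulated genes, against 81.2% of the real genes with a mean of at least 1 RPKM. The simulation therefore does not match all real genes, and its recovery of counts does not carry over to them. In the simulated root comparison 40.8% of 49 genes changed 2-fold, 97.9% of 48 changed 3-fold and 100% of 49 changed 4-fold passed the size threshold, as did 1.84% of 14285 unchanged genes. In the simulated leaf comparison these shares were 47.9% of 48, 91.5% of 47 and 100% of 49 genes, and 3.01% of 13125 unchanged genes. The list step was checked on the real ratios instead. Of 200 random lists of 25 genes, 3% stood apart in root and 4.5% in leaf, a share that the percentile limits set by construction. This says nothing about lists of related genes. With 0.5 added to each member's log2 ratio, 97.5% and 89.5% stood high. The simulation draws counting error alone and holds no differences between plants. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.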

Results

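Gene expression was measured in 4 libraries, 1 per group, from roots and leaves of 28-day-old cucumber plants fed 5 mM nitrate (control) or 1 mM nitrate (low nitrogen). Values above 0 were listed for 17054 genes in root control, 17141 in root low nitrogen, 15762 in leaf control and 16234 in leaf low nitrogen. The depths behind them were 4.23, 3.98, 2.93 and 2.74 M reads (M for mega). The 20 genes with the highest mean over all 4 libraries took 8.67% of the RPKM sum in root control, 9.18% in root low nitrogen, 29.1% in leaf control and 22.2% in leaf low nitrogen. These are not the 20 highest genes of each library. Across genes, which are not independent replicates, log2 values of the root libraries had a Pearson correlation of 0.959 and those of the leaf libraries 0.955, while pairs of a root and a leaf library lay between 0.618 and 0.639.

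The first question was how roots supplied with little nitrogen differed from control roots. Nitrate uptake genes differed in opposite directions. NRT1.1 (AT1G12110, scaffold02951), the homologue of the dual-affinity nitrate transporter and sensor, was at 235 RPKM in control root and 11.03 in low nitrogen root, 21.3-fold lower with a counting interval of 15.9 to 29.2. NRT2.5 (AT1G12940), of the high-affinity nitrate transporters, was at 0.15 and 19.6 RPKM, a ratio of 130.5 that rests on 1 control read and has a counting interval of 22.5 to 5082. The ammonium transporters ATAMT1;2 (AT1G64780, scaffold01227, 11.1 and 33.7 RPKM) and ATAMT2 (AT2G38290, scaffold01225, 16.6 and 44.7 RPKM) were higher in low nitrogen root. The lists of aquaporins and phosphate starvation genes stood low in low nitrogen root. The ethylene list stood high, with 12 of 44 genes higher, but not among genes with a mean of at least 5 RPKM.

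Of 14532 genes compared in root, 897 were higher in low nitrogen and 631 lower by a log2 ratio of at least 1, and the median log2 ratio was 0.04. With counting error alone, 1.84% of unchanged genes passed this threshold in simulated data. Counts were recovered for 731 of the higher and 496 of the lower genes; the counting interval excluded 1 for 613 and 408 of them. The difference between the libraries has no replicate check, so plant-to-plant variation is not separated from the effect of the solution.

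The 10 highest genes with a symbol in low nitrogen root began with FHIT (AT5G58240, scaffold03080), homologous to a nucleotide hydrolase, which was listed at 0 in control and 53.1 RPKM in low nitrogen root, at least 8.15-fold higher. The class III peroxidase homologue RCI3A (AT1G05260) was at 0.23 and 50.7 RPKM, a ratio of 220.4 resting on 1 control read (counting interval 38.3 to 8568). Expansin-like genes, of a family of cell wall proteins, held 4 of the 10 places, each listed at 0 in control root: EXPL1 (AT3G45970, scaffold03577) at 21.6 RPKM, EXPL2 (AT4G38400, scaffold00926) at 18.7, a second EXPL2 copy on the same scaffold at 15.3 and EXPL1 (AT3G45970, scaffold00926) at 13.4 in low nitrogen root. These were at least 36.5-fold, 22.7-fold, 3.19-fold and 4.61-fold higher, and members of one family may share reads. Alcohol dehydrogenase ATADH1 (AT1G77120, scaffold00793), of ethanolic fermentation, was at 44.3 and 813 RPKM, 18.4-fold higher with a counting interval of 16.3 to 20.7. TL2 (AT3G16720, scaffold00089), homologous to a RING-type ubiquitin ligase, was at 1.26 and 33.3 RPKM, and the ACC oxidase ATACO1 (AT2G19590), of ethylene synthesis, at 12.1 and 162 RPKM. Genes without a symbol ranked among these 8 times. The highest of them, a homologue of AT3G29970 on scaffold01221, was at 0.90 and 706 RPKM, with 1 control read and a ratio of 784 (counting interval 141 to 31165).

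The lowest gene in low nitrogen root was MEE66 (AT2G02240, scaffold00557), at 765 RPKM in control and 7.55 in low nitrogen root, 101-fold lower (counting interval 63.0 to 174). After NRT1.1 came the defensin homologue PDF1.4 (AT1G19610, scaffold03356, 261 and 14.6 RPKM) and the sulfate transporter homologue SULTR3;5 (AT5G19600, 51.4 and 2.84 RPKM). NAS1 (AT5G04950), a nicotianamine synthase of metal transport, was at 43.9 and 2.75 RPKM, and a second PDF1.4 copy (AT1G19610, scaffold03356) at 28.8 and 1.64 RPKM. SPX3 (AT2G45130), of phosphate signalling, was at 66.7 and 5.66 RPKM. The list ended with the beta-glucosidase BGLU12 (AT5G42260, scaffold01079, 42.1 and 3.85 RPKM), the glycosyltransferase UGT88A1 (AT3G16520, 54.2 and 5.28 RPKM) and the sulfur response gene LSU2 (AT5G24660, 20.9 and 1.64 RPKM). LSU2 had 2 reads in low nitrogen root and a ratio of 12.7 (counting interval 3.19 to 110.2). Genes without a symbol ranked among the lowest 8 times, led by a gene without a homologue on scaffold03904, at 39.1 RPKM in control and listed at 0 in low nitrogen root, at least 5.96-fold lower.

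Within nitrogen metabolism, root nitrite reductase NIR1 (AT2G15620) was at 150.5 RPKM in control and 43.9 in low nitrogen, and nitrate reductase NR2 (AT1G37130) at 82.8 and 79.4 RPKM. The nitrate and nitrite reduction list had 0 members higher and 2 lower of 8, with a median log2 ratio of -0.32 at the 4.48th percentile, inside the random range. The second lower member was a nitrate reductase copy, NR1 (AT1G77760, scaffold02541), too low for the naming rule, at 4.53 and 0.08 RPKM with 1 low nitrogen read. The other genes lay between -0.38 for CNX3 (AT1G01290) and 0.17 for SIR1 (AT5G55130), both of molybdenum cofactor synthesis. Genes that supply reducing power to nitrite reductase in roots were at 439 and 105 RPKM for the ferredoxin FD3 (AT2G27510, scaffold01365), 98.5 and 29.03 RPKM for the ferredoxin reductase RFNR1 (AT4G05390) and 20.6 and 4.59 RPKM for the dehydrogenase G6PD1 (AT5G35790). That list had 1 member higher and 4 lower of 9 and a median of -0.14. Its median was -0.64, at the 0.02th percentile, when genes with the same homologue were summed. High-affinity nitrate transport had 2 measured members that went opposite ways, NRT2.5 and NRT2.4 (AT5G60770, 48.6 and 22.1 RPKM); their median of 1.53 lay at the 99.25th percentile, and at the 95.7th with a pseudocount of 5.

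Ammonium transport stood apart on the high side in root, with 2 of 4 members higher, 0 lower and a median of 0.84; ATAMT1;1 (AT4G13510, scaffold01337) was at 50.8 and 62.6 RPKM. Without a filter on low values this list lay at the 85.7th percentile. Ammonium assimilation had a median of 0.01, with 2 of 12 members higher and 1 lower. The ferredoxin-dependent glutamate synthase GLUS (AT5G04140) was at 25.4 and 73.6 RPKM, glutamate dehydrogenase GDH1 (AT5G18170) at 38.1 and 90.0, asparagine synthetase ASN2 (AT5G65010) at 69.1 and 113 and the cytosolic glutamine synthetases GSR 1 (AT5G37600) at 18.6 and 4.35 on scaffold00444 and at 502 and 613 on scaffold03746. Nitrate and peptide transport had a median of -0.11 with 2 higher and 2 lower of 13; of the NRT1.5 homologues (AT1G32450), whose Arabidopsis counterpart loads nitrate into the xylem, the one on scaffold02229 was at 47.9 and 148 RPKM and the one on scaffold02995 at 25.8 and 7.90. Nitrogen signalling regulators had a median of -0.15 with 1 higher and 3 lower of 20, among them the repressor LBD37 (AT5G67420, 28.1 and 7.16 RPKM) and TGA1 (AT5G65210, 99.7 and 45.9 RPKM).

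**Figure D1:**
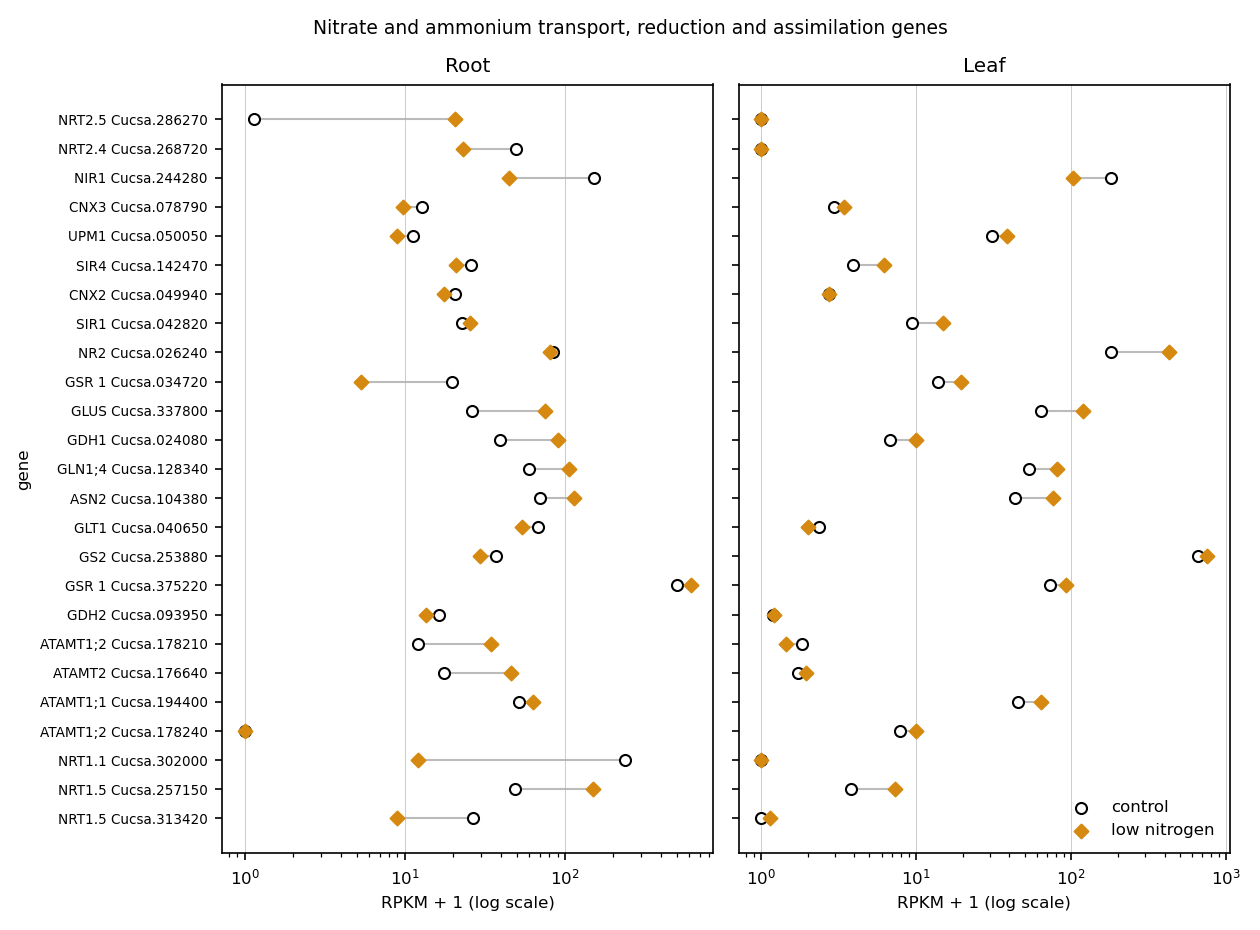
RPKM + 1 on a log scale for genes of nitrate and ammonium transport, reduction and assimilation in root (left) and leaf (right); open circles are the control library and diamonds the low nitrogen library, 1 library each. In root NRT1.1 (scaffold02951) lies at 235 RPKM in control and 11.03 in low nitrogen, and NRT2.5 at 0.15 and 19.6.

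Aquaporins, the water channels of plasma membrane and tonoplast, had 0 members higher and 7 lower of 23 in root, with a median of -0.64 at the 0.01th percentile. TIP2;2 (AT4G17340) was at 1266 and 529 RPKM, PIP2A (AT3G53420, scaffold01001) at 293 and 130.4 and TMP-B (AT1G01620, scaffold00787) at 119 and 40 RPKM. Phosphate starvation genes had 2 higher and 12 lower of 32 and a median of -0.46, below all 10000 random lists; SPX2 (AT2G26660, scaffold01037) was at 45.4 and 6.96 RPKM and the acid phosphatase PAP12 (AT2G27190) at 37.1 and 5.11. Sulfur uptake and assimilation had 2 higher and 4 lower of 28 and a median of -0.28 at the 0.48th percentile. Its member CYSC1 (AT3G61440) was at 41.5 and 147 RPKM. The low nitrogen solution held more sulfate. Heat shock and protein folding genes had a median of -0.16 at the 1.28th percentile, with 1 higher and 3 lower of 56, including J8 (AT1G80920) at 519.9 and 198 RPKM. Potassium and chloride transport had a median of -0.17, on the 2.5th percentile, with 2 higher and 4 lower of 37; it stood apart in 3 of 10 alternatives.

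On the high side, 12 of 44 ethylene genes were higher in low nitrogen root and 3 lower, with a median of 0.30 at the 99.9th percentile. Beside ATACO1, the response factor ERF1 (AT3G23240, scaffold00581) was at 7.30 and 47.4 RPKM and the ethylene-forming enzyme EFE (AT1G05010, scaffold00542) at 61.8 and 298. The list lay at the 93.7th percentile among genes with a mean of at least 5 RPKM. Phenylpropanoid and flavonoid synthesis had 5 higher and 1 lower of 21 and a median of 0.34 at the 98.7th percentile, with phenylalanine ammonia-lyase PAL1 (AT2G37040, scaffold01001) at 17.1 and 41.5 RPKM; it stood apart in 6 of 10 alternatives. In all, 4 of 42 lists stood high and 5 low, where 2.1 lists of randomly drawn genes would lie outside the limits. How many would do so between 2 libraries of the same treatment is not known.

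Within the random range in root were starch and sucrose metabolism (median 0.21), where sucrose synthase SUS4 (AT3G43190) was at 3.02 and 33.5 RPKM, and iron uptake and storage (median -0.13), where 2 were higher and 10 lower of 32, among them the nicotianamine synthase NAS4 (AT1G56430, scaffold00894, 55.5 and 8.13 RPKM) and the ferric reductase FRO4 (AT5G23980, 12.6 and 1.30 RPKM). Iron genes lay at the 2.29th percentile when genes with the same homologue were summed. Class III peroxidases had a median of -0.03 with 7 higher and 5 lower of 30, PA2 (AT5G06720, scaffold01124) being at 458 and 74.95 RPKM, and cell wall loosening and remodelling had a median of 0.04 with 10 higher and 8 lower of 74. Hormone lists had medians of 0.04 for cytokinin, 0.01 for auxin, 0.00 for abscisic acid, 0.12 for jasmonate and -0.08 for gibberellin. The abscisic acid receptor homologue RCAR10 (AT2G38310, scaffold01044) was at 4.92 and 46.3 RPKM, and the cytokinin oxidase CKX7 (AT5G21482) at 43.9 and 9.22. Medians were 0.09 for amino acid transport, 0.14 for nitrogen salvage, -0.08 for organic acid metabolism, 0.09 for lignin synthesis, 0.06 for senescence and autophagy, -0.04 for defence and 0.08 for oxidative stress. The tonoplast malate transporter homologue TDT (AT5G47560, scaffold00032) was at 115 and 14.6 RPKM in root. They were 0.13 for histones and cell cycle, 0.07 for clock and light signalling, 0.00 for mitochondrial respiration, -0.09 for cytosolic and -0.03 for plastid ribosomal proteins, 0.05 for the Calvin cycle, -0.14 for chlorophyll synthesis and -0.27 for chlorophyll breakdown. Markers of other organs and cell types lay inside the random range in root as well, with medians of 0.15 for photosystems, 0.33 for leaf epidermis and polarity, 0.06 for phloem proteins and -0.05 for root cell types.

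The second question was how leaves on little nitrogen differed from control leaves. The histone and cell cycle list stood high in low nitrogen leaf and the photosynthesis lists stood low. The cyclin CYCA1;1 (AT1G44110) was at 1.48 RPKM in control leaf and 30.0 in low nitrogen leaf, 20.3-fold higher with a counting interval of 10.4 to 45.03. Rubisco activase RCA (AT2G39730, scaffold01153) was at 2231 and 509 RPKM, and the antenna protein LHCB4.1 (AT5G01530) at 3209 and 959. The phosphate starvation list stood low in leaf, as in root. Nitrate reductase NR2 was at 179.9 and 425 RPKM, while nitrite reductase NIR1 was at 179 and 102.

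Of 13384 genes compared in leaf, 1816 were higher and 481 lower, so 79.1% of these were higher. The median log2 ratio of all genes was 0.33, and relative to that median 791 genes were higher and 1005 lower, a share of 44.0%. The share was 39.9% with median ratio scaling (827 higher, 1245 lower), 56.8% with upper quartile scaling (1099 and 835), 81.8% with equal sums (2385 and 532) and 73.2% without the 20 highest genes (2109 and 771). Whether more genes were higher or lower in low nitrogen leaf therefore depended on the scaling, and list medians below are given relative to the median of all genes. Counts of list members higher and lower are those of the values as deposited and depend on the scaling too. As in root, the difference has no replicate check; the counting interval excluded 1 for 1260 of the 1463 higher and 283 of the 381 lower genes with counts.

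**Figure D2:**
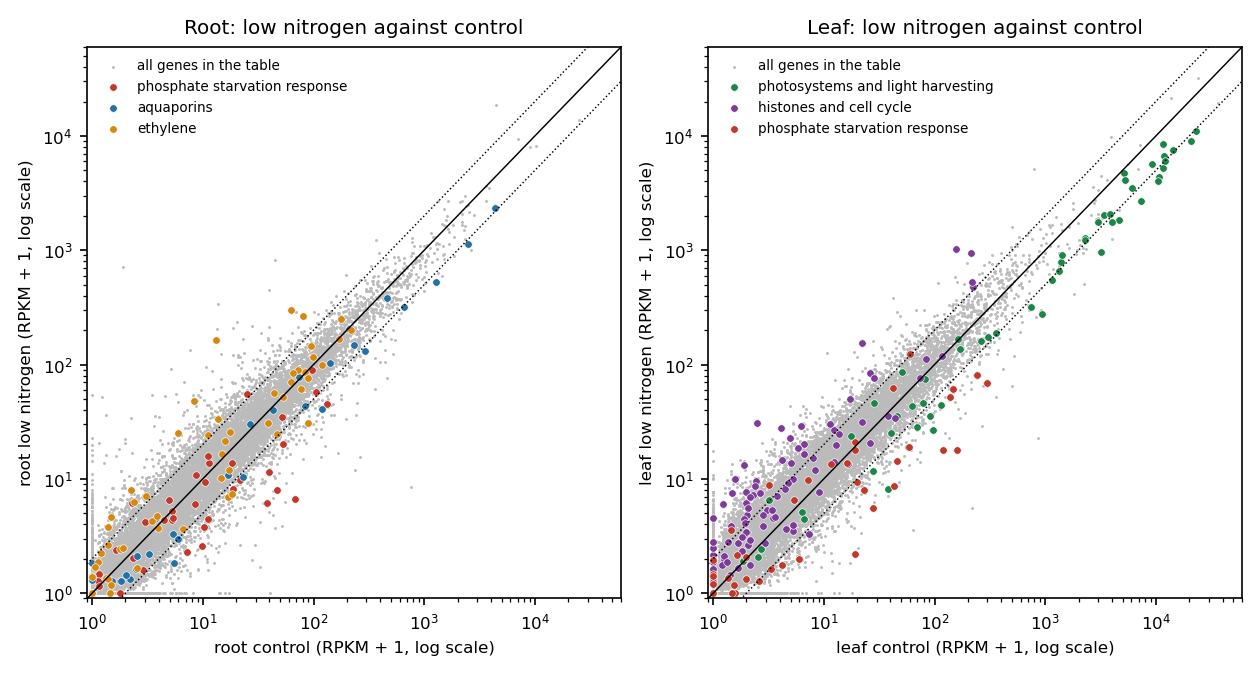
RPKM + 1 of each gene in low nitrogen against control, on log scales, for root (left) and leaf (right), 1 library per axis; the solid line marks equal values and the dotted lines a log2 ratio of 1 and -1. In root 7 of 23 aquaporins lie at or below a log2 ratio of -1, and in leaf 20 of 53 photosystem genes do, while 37 of 74 histone and cell cycle genes lie at or above 1 with the values as deposited.

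The highest gene with a symbol in low nitrogen leaf was RSM2 (AT4G39250, scaffold03806), of a small MYB-related family, listed at 0 in control leaf and 16.5 RPKM in low nitrogen leaf, at least 3.93-fold higher. After CYCA1;1 came THIC (AT2G29630), of thiamine synthesis, at 41.5 and 379 RPKM, 9.14-fold higher (counting interval 8.22 to 10.2). OFP8 (AT5G19650, scaffold00995) was at 0.75 and 13.7 RPKM, a ratio of 18.2 on 1 control read (counting interval 2.85 to 761). MEE68 (AT4G24660, scaffold00927) was at 0.46 and 10.8 RPKM and the acyltransferase LPAT2 (AT3G57650, scaffold01079) at 0.89 and 13.4, the latter with 3 control reads and a ratio of 15.1 (4.80 to 75.7). The histone chaperone homologue SGA1 (AT5G38110) was at 1.79 and 19.4 RPKM, the mitotic cyclin CYCB1;2 (AT5G06150) at 0.88 and 12.1, histone H2A HTA12 (AT5G02560, scaffold03837) at 21.2 and 153 and the clock gene ELF4 (AT2G40080) at 17.8 and 127. Genes without a symbol ranked among these 5 times.

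MEE66 (scaffold00557) was also the lowest named gene in low nitrogen leaf, at 219 RPKM in control and 4.52 in low nitrogen, 48.5-fold lower (counting interval 23.3 to 122). Galactinol synthase GolS4 (AT1G60470), of raffinose synthesis, was at 63.4 and 2.56 RPKM. The late embryogenesis gene LEA4-5 (AT5G06760, scaffold02047) was at 11.5 RPKM and listed at 0 in low nitrogen leaf, at least 3.11-fold lower. The phloem lectin PP2-A1 (AT4G19840, scaffold01154) was at 266 and 28.0 RPKM, SPX3 at 159 and 16.9 and TDT (scaffold00032) at 19.4 and 1.48. The purple acid phosphatases PAP23 (AT4G13700) and PAP3 (AT1G14700) were at 18.0 and 1.21 RPKM and at 118 and 17.0 RPKM. COL2 (AT3G02380), of the CONSTANS-like family, was at 20.7 and 2.37 RPKM. NUDX1 (AT1G68760, scaffold02653) was at 10.9 and 0.90 RPKM, a ratio of 12.1 on 2 low nitrogen reads (counting interval 3.04 to 105). Genes without a symbol ranked among the lowest 8 times, led by a gene without a homologue on scaffold01001, at 859 and 21.8 RPKM.

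Histones and cell cycle had 37 of 74 members higher and 1 lower in low nitrogen leaf (31 and 1 of 75 with median ratio scaling), and a median 0.67 above that of all genes, higher than all 10000 random lists. Photosystems and light harvesting had 1 member higher and 20 lower of 53, against 0 and 37 of 54 with median ratio scaling and 0 and 33 of 53 with upper quartile scaling. Its median was -1.17 relative to all genes; the antenna genes LHCA2 (AT3G61470) and LHCB1.4 (AT2G34430, scaffold01543) were at 37.2 and 7.08 RPKM and at 96.1 and 25.8 RPKM. The Calvin cycle and photorespiration list lay at -1.02, with 1 higher and 9 lower of 28, among them the plastid dehydrogenase GAPB (AT1G42970) at 897 and 289.6 RPKM. Both lists lay below all random lists, and both kept medians below 0 under each scaling. Chlorophyll synthesis lay at -0.54, with 0 higher and 1 lower of 18, CHLM (AT4G25080) being at 382 and 168 RPKM. Cytosolic ribosomal proteins lay at 0.29, with 8 of 35 higher and 0 lower, including RPL24A (AT2G36620, scaffold01001) at 51.3 and 145.15 RPKM.

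Phosphate starvation genes lay at -1.57 relative to all genes, with 3 higher and 16 lower of 27. Class III peroxidases lay at -1.21 with 2 higher and 6 lower of 12, PA2 (scaffold01124) being at 243 and 75.2 RPKM. Aquaporins lay at -0.50 with 1 higher and 3 lower of 19; TIP1;1 (AT2G36830, scaffold01001) was at 2205 and 943 RPKM in leaf and at 2466 and 1123 in root. Oxidative stress genes lay at -0.33 with 5 higher and 3 lower of 68; their own median was 0.00 and changed sign between scalings, and the list lay at the 3.27th percentile when genes with the same homologue were summed. The list on NADPH supply for nitrite reduction lay at -0.52, with 0 higher and 2 lower of 9, and at the 5.32th percentile among genes with a mean of at least 5 RPKM. Gibberellin genes lay at 0.36 with 6 higher and 3 lower of 26, GASA3 (AT4G09600, scaffold00923), a gibberellin-regulated peptide gene, being at 45.1 and 285 RPKM and KAO2 (AT2G32440, scaffold02995), of gibberellin synthesis, at 122 and 51.2. This list lay at the 83.3th percentile among genes with a mean of at least 5 RPKM. Leaf epidermis and polarity genes lay at 0.31 with 7 higher and 0 lower of 33, with the epidermal gene PDF1 (AT2G42840) at 43.0 and 161 RPKM; they stood apart in 7 of 10 alternatives. In leaf, 4 of 41 lists stood high and 8 low, where 2.05 lists of randomly drawn genes would lie outside the limits. As in root, the number between 2 libraries of the same treatment is not known.

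**Figure D3:**
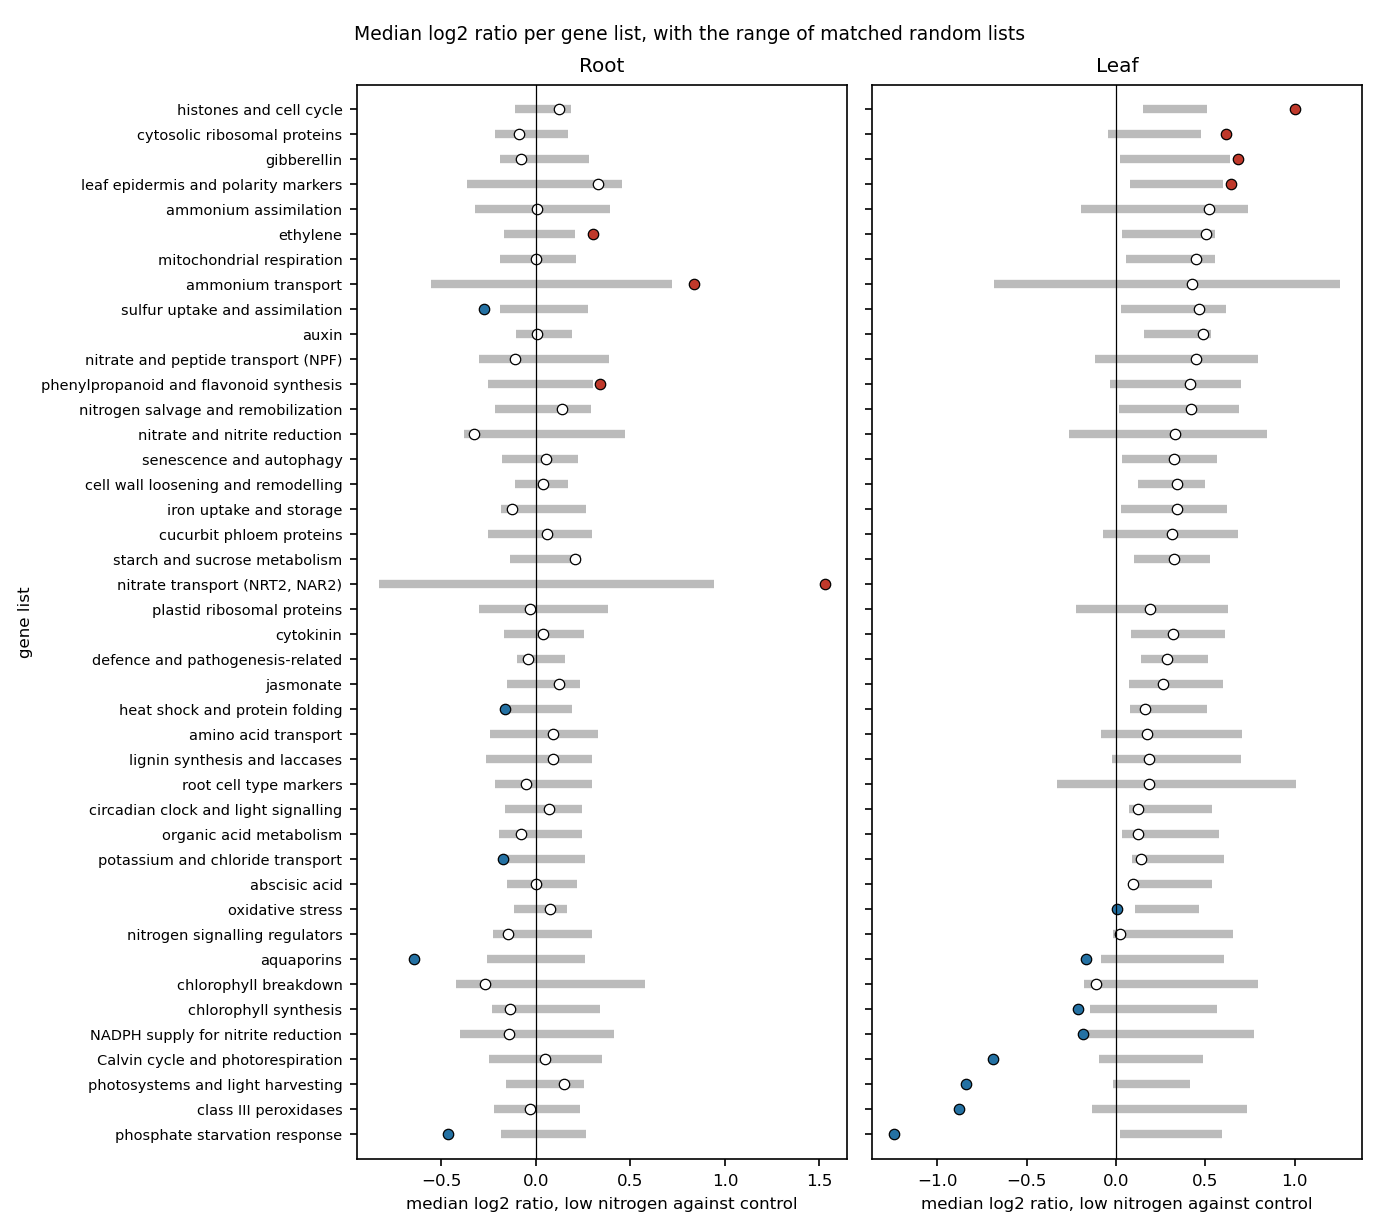
Median log2 ratio of each gene list in low nitrogen against control for root (left) and leaf (right), from 1 library per group; grey bars span the central 95% of the medians of 10000 matched random lists, red points stand above and blue points below them, and open points lie within. In root 4 of 42 lists stand high and 5 low, and in leaf 4 of 41 stand high and 8 low.

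The nitrogen lists lay inside the random range in leaf, with medians relative to all genes of 0.12 for nitrate and peptide transport, 0.00 for nitrate and nitrite reduction, 0.19 for ammonium assimilation, 0.10 for the 2 measured ammonium transporters, -0.16 for amino acid transport, 0.09 for nitrogen salvage and -0.31 for nitrogen signalling regulators, which stood low in 2 of 10 alternatives. The high-affinity nitrate transporters were listed at 0 in both leaf libraries. Glutamate synthase GLUS was at 62.5 and 119 RPKM in leaf, and the plastid glutamine synthetase GS2 (AT5G35630) at 655 and 753. Phenylpropanoid and flavonoid synthesis lay at 0.09, with 7 higher and 4 lower of 16: chalcone synthase TT4 (AT5G13930) was at 54.2 and 226 RPKM and another PAL1 copy (AT2G37040, scaffold01001) at 23.4 and 9.81. Ethylene genes lay at 0.18 with 6 higher and 0 lower of 32, and stood high in 5 of 10 alternatives; ERF1 (scaffold00581) was at 1.82 and 11.3 RPKM. Abscisic acid genes lay at -0.23 and stood low in 5 of 10 alternatives. Clock and light signalling lay at -0.21 with 8 higher and 3 lower of 40, and stood low in 3 of 10.

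The remaining leaf lists were inside the random range, with medians relative to all genes of 0.16 for auxin, -0.01 for cytokinin, -0.06 for jasmonate, 0.14 for sulfur, 0.01 for iron, 0.01 for cell wall remodelling, -0.01 for starch and sucrose, -0.15 for lignin synthesis and -0.04 for defence. They were -0.17 for heat shock, -0.21 for organic acid metabolism, -0.44 for chlorophyll breakdown, -0.14 for plastid ribosomal proteins and 0.12 for mitochondrial respiration. Potassium and chloride transport lay at -0.19 and stood low in 1 of 10 alternatives. Senescence and autophagy had 3 higher and 1 lower of 31 and a median of 0.33, equal to that of all genes to 2 decimals; NAP (AT1G69490), a senescence regulator, was at 5.96 and 22.9 RPKM and SEN1 (AT4G35770) at 215 and 68.7. Root cell type markers (-0.15, 5 measured) and phloem proteins (-0.01) were inside the range too.

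Leaf and root were compared in the control libraries to describe the organs and check the labels. The antenna gene LHCB1.4 (AT2G34430, scaffold00542) was at 2.60 RPKM in root and 22999.6 in leaf, plastocyanin PETE2 (AT1G20340) at 4.93 and 11969, the plastid aldolase FBA1 (AT2G21330) at 0.45 and 2968 and the thiazole synthase TZ (AT5G54770) at 2.08 and 5601. FMO1 (AT1G19250, scaffold00485) was listed at 0 in root and 2872 RPKM in leaf. Highest in root were the latex protein homologues MLP34 (AT1G70850, scaffold00164), at 10282 RPKM and listed at 0 in leaf, and MLP423 (AT1G24020, scaffold00714), at 1023 and listed at 0, with UBQ9 (AT5G37640) at 25232 and 7.41, AGO3 (AT1G31290) at 1854 and 0.26 and ELP (AT1G12090, scaffold02951) at 761 and listed at 0. Both tissue labels fit these levels of photosynthesis genes: the median photosystem gene was at 2.71 RPKM in root control and 555 in leaf control. Of 14711 genes, 2589 were higher in leaf and 5950 lower, with a median log2 ratio of -0.65; relative to that median 3899 were higher and 3754 lower, and with median ratio scaling 3772 and 4042. In the low nitrogen libraries 3018 of 15057 genes were higher in leaf and 4694 lower, with a median of -0.30. Relative to that median the counts were 3719 and 3788.

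The last question was whether both organs differed from their controls in the same genes. MEE66, SPX3, TDT and the aquaporin TIP1;1 (scaffold01001, log2 ratios -1.13 and -1.22) were lower in both. Of 14975 genes, 162 were higher in low nitrogen in both organs, where independent lists would share 109, and 73 were lower in both, against 20.3. Opposite directions were found for 38 genes higher in root and lower in leaf, against 29.3, and 40 lower in root and higher in leaf, against 75.6. These counts depend on the scaling: with the median over all genes subtracted they were 86 higher in both, 118 lower in both, 59 and 24. Across genes, which are not replicates, the root and leaf log2 ratios had a Pearson correlation of 0.15 and a Spearman correlation of 0.15. The leaf ratio exceeded the root ratio by at least 1 for 2477 genes and lay below it by at least 1 for 1053.

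The named genes with the largest leaf minus root difference were NRT1.1 (scaffold02951), PDF1.4 (scaffold03356) and SULTR3;5, lower in low nitrogen root and at most at 1.84 RPKM in leaf, with RTFL12 (AT4G13395), of a family of small peptides, and CYCA1;1. RTFL12 was at 72.8 and 20.7 RPKM in root and at 2.62 and 19.2 in leaf. At the other end were FHIT (scaffold03080), RCI3A and EXPL1 (scaffold03577), higher in low nitrogen root and at or below 0.85 RPKM in leaf. TL2 (scaffold00089) was at 2.77 and 0.59 RPKM in leaf. A second ATADH1 copy (AT1G77120, scaffold00793) was at 38.5 and 450.4 RPKM in root and at 6.58 and 2.52 in leaf. The difference between organs was not tested, since each rests on 1 library per group.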

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

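The genes below were picked out because they were at or beyond a log2 ratio of 1 in root and in leaf, in opposite directions, among the genes named by rule; no test was chosen after seeing them. The difference between organs was not tested for any of them, since each ratio rests on 1 library per group. Values of leaf minus root are differences of log2 ratios, low nitrogen against control.

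TL2 (AT3G16720, scaffold00089), homologous to a RING-type ubiquitin ligase, had a log2 ratio of 3.92 in root and -1.25 in leaf, a leaf minus root difference of -5.17. An alcohol dehydrogenase copy, ATADH1 (AT1G77120, scaffold00793; 38.5 and 450.4 RPKM in root), had ratios of 3.52 and -1.11 and a difference of -4.62. A class III peroxidase homologue without a symbol (AT2G41480, scaffold01658) was at 7.96 and 53.6 RPKM in control and low nitrogen root and at 10.6 and 1.26 RPKM in leaf, a difference of -4.97. Another PAL1 copy (AT2G37040, scaffold01001), a phenylalanine ammonia-lyase, was at 8.99 and 19.5 RPKM in root and at 5.31 and 1.67 in leaf, apart from the copies named above; it had ratios of 1.03 and -1.24 and a difference of -2.28. In the other direction, RTFL12 (AT4G13395) had ratios of -1.76 in root and 2.48 in leaf, a difference of 4.24. The jasmonate signalling repressor homologue TIFY9 (AT5G13220, scaffold00919) had ratios of -1.24 and 1.48 and a difference of 2.72. With the planned pseudocount of 5, TL2 (-0.48 in leaf), ATADH1 (-0.62 in leaf), PAL1 (0.81 in root, -0.63 in leaf) and TIFY9 (-0.79 in root) lay within a log2 ratio of 1 in at least 1 organ, so they would not have been picked out; RTFL12 and the peroxidase homologue would.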

How the results depend on the processing

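The ratios minus the median over all genes and the summing of genes with the same homologue were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each group had 1 library and the labels give no replicate numbers. A fit blocked on organ was not made, since its only residual is the difference between organs and holds no variation between plants. Of the summary values under the alternatives, 127 stayed within 1.5 times the reported count, or within the bootstrap interval over genes of a correlation, and 51 moved. For the 286 named gene ratios, 1731 values under the alternatives were unchanged or stayed within their counting interval, and 552 moved. Changed values of genes without an interval were counted as moved, and the filters on low values leave a ratio unchanged by construction. A change of direction was looked for only in ratios at or beyond the threshold, and none was found. Pseudocounts and filters cannot change a direction, so this says little. Of the lists standing apart, 4 in root (aquaporins, phosphate, sulfur, heat shock) and 8 in leaf (photosystems, Calvin cycle, chlorophyll synthesis, phosphate, aquaporins, class III peroxidases, histones and cell cycle, cytosolic ribosomal proteins) did so under every alternative tried. Of list values, 20 moved into the random range and 18 out of it, and 1 is given below. The rest kept their standing as high, low or within the random range. Lists that stayed within that range count as kept even where their median crossed that of random lists.

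With a pseudocount of 0.1, 385 genes were higher in both organs, 157 lower in both, 108 higher in root and lower in leaf and 174 the opposite, and the Pearson correlation across genes was 0.11 (0.109). A pseudocount of 5, which shrinks the ratios of low genes by construction, gave 376 higher and 267 lower genes in root, 604 and 199 in leaf, and 28, 34, 7 and 2 in the same 4 classes. With no filter the Spearman correlation was 0.12 (0.124) and 2 root lists stood high. A mean of at least 5 RPKM, which leaves fewer genes, gave 411 lower genes in root, 1109 higher and 290 lower in leaf, 106 higher in both organs, 23 and 15 in opposite directions, correlations of 0.185 (Pearson) and 0.18 (Spearman), and 2 leaf lists standing high.

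Median ratio scaling gave 827 higher and 1245 lower genes in leaf, with 76 higher in both organs, 146 lower in both, 59 higher in root and lower in leaf and 23 the opposite. Upper quartile scaling gave 1099 and 835 in leaf, 100 higher in both and 114 lower in both. Scaling to equal sums gave 77 lower in root and higher in leaf. Without the 20 highest genes 771 were lower in leaf, 112 lower in both, 80 and 79 in opposite directions, with correlations of 0.128 and 0.133. Requiring the counting interval to exclude 1, possible only where counts were recovered, left 408 lower genes in root and 283 in leaf. Ratios minus the median gave 791 and 1005 in leaf, 3899 and 3754 between control leaf and root, and 86, 118, 59 and 24 in the 4 classes. The scalings move all genes of a library together, which by construction changes the balance of higher and lower genes.

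When genes with the same homologue were summed, the root class III peroxidases lay 0.48 above random lists, against -0.03 reported as the median of single genes; the cause was not tested. Depth limits genes with few reads: the floor of 3 reads at 1 kb was 0.71 RPKM in root control, 0.75 in root low nitrogen, 1.02 in leaf control and 1.10 in leaf low nitrogen.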

Other observations

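The scalings and the histone, photosystem and phosphate starvation lists were planned. The tests with low-oxygen, early leaf growth and clock genes, those on shared reads and phosphate supply, and the bounds used to judge the scalings were chosen only after the results they bear on had been seen in whole or in part. The criterion for the hour of sampling and the wording on aeration were also rewritten after a first result. Single genes named below outside the naming rule were chosen after their values were seen.

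A list of genes known to be induced by low oxygen in Arabidopsis stood high in the low nitrogen root library. This list was written from textbook knowledge after the highest root genes had been seen, and 7 of its 45 cucumber genes are also in the lists of the comparisons above. Of 41 measured genes 21 were higher and 3 lower, with a median log2 ratio of 1.24, above all 10000 random lists. Pyruvate decarboxylase PDC2 (AT5G54960), of ethanolic fermentation, was at 22.6 RPKM in control and 125 in low nitrogen root, the third ATADH1 copy (AT1G77120, scaffold02463) at 0.29 and 12.8 and the regulator LBD41 (AT3G02550, scaffold01357) at 37.96 and 99.8. The other LBD41 copy went the other way, at 5.87 and 4.05 RPKM. The 3 lower genes were a CML38 copy (AT1G76650, 210 and 93.7 RPKM), a PHI-1 copy (AT1G35140, 113 and 55.1) and the homologue of AT3G23170 (14.05 and 4.91). The homologues of plant cysteine oxidases, AT5G15120 and AT5G39890, were at 5.74 and 69.0 RPKM and at 19.9 and 114. Among the 25 measured genes that had not been seen first, 7 were higher and 3 lower, with a median of 0.38 at the 99.7th percentile; the most abundant of the list, the haemoglobin NSHB1 (AT2G16060), was at 7011 and 9361 RPKM.

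Evening-phased clock genes were higher in the low nitrogen leaf library for 6 of 10 measured genes, with 0 lower (4 of 11 and 0 with median ratio scaling). Of the 12 genes of this list 11 are also in the lists of the comparisons above, and ELF4 had been seen among the highest leaf genes. The GIGANTEA homologues GI (AT1G22770, scaffold00793 and scaffold03611) were at 27.7 and 81.6 RPKM and at 62.1 and 193, and TOC1 (AT5G61380) at 6.89 and 19.1. Members within the threshold included FKF1 (AT1G68050), at 25.85 and 34.07 RPKM, and FIO1 (AT2G21070), at 5.12 and 7.34. Of the morning genes, LHY1 (AT1G01060) was at 7.56 and 3.56 RPKM, while RVE1 (AT5G17300), below the filter on low values, went the other way, at 0.30 and 1.44. In root these evening genes had 0 members higher and 0 lower of 11.

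The high median of the low-oxygen list in root was weighed first. The median stayed at 1.13 or above under 5 scalings (0.33 or above without the genes seen first). This is no test of scaling, as the 5 scalings left the root median of all genes between -0.01 and 0.07. That range is too narrow to bring the list to 0. The scalings show only that the list stayed above all random lists. Reads shared between genes with the same homologue are argued against as the whole source. Genes that alone match their homologue had a median of 0.57 over 21 genes. Over the 15 not seen first it was 0.42, at the 99.01th percentile, with 3 higher and 1 lower. Family members with different homologues may share reads too, which was not tested. Poor aeration of the pot of this root sample, apart from nitrogen, may also give such a pattern and cannot be told apart from the solution with 1 root library per treatment; in leaf the list's median lay 0.079 above that of random lists. An effect of low nitrogen on these genes stays open as an untested hypothesis.

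The second pattern was a high median of the histone and cell cycle list, with 37 of 74 genes higher, and a low median of the photosystem list, with 20 of 53 lower, in low nitrogen leaf. Under 5 scalings the histone and cell cycle median stayed at 0.62 or above and the photosystem median at -0.77 or below. These scalings left the leaf median of all genes between -0.05 and 0.39, too narrow a range to bring either list's median to 0. They show only that the 2 lists lay above and below all matched random lists whichever scaling was used. More young, dividing leaf tissue in the low nitrogen sample is a candidate explanation. Genes of early leaf growth lay at the 99.96th percentile of random lists in leaf and at the 99.81th or above under the other scalings. Of this list, 9 of 22 were higher and 0 lower as deposited, but 3 and 3 of 23 with median ratio scaling. The 17 measured genes outside the other lists had a median 0.59 above that of all genes in leaf. In root 19 genes of the list were measured, with 2 higher and 0 lower. Their median of 0.28 lay at the 93.9th percentile, inside the random range. Of the list's most abundant genes, GIF1 (AT5G28640) was at 29.6 and 70.7 RPKM in leaf but also at 8.97 and 23.1 in root, so its rise was not particular to leaf. In leaf YAB5 (AT2G26580, scaffold01037) was at 34.7 and 46.5 RPKM and TCP14 (AT3G47620, scaffold02653), lower by less than the threshold, at 56.6 and 36.0. Another hour of sampling cannot be told apart from more young leaf tissue: evening clock genes had a median 0.95 above that of random lists, but they were almost all in lists seen before, only 1 morning gene passed the filter in leaf, and RVE1 below it went the other way. A direct effect of low nitrogen stays open, untested.

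The third pattern was a low median of the phosphate starvation list in both organs, with 12 of 32 genes lower in root, 16 of 27 in leaf and 8 of 26 in both. The highest median over 5 scalings and both organs was -0.45. This is no test of scaling, as the 5 scalings moved the median of all genes too little to bring the list to 0. They show only that the list stayed below all random lists. Reads shared between genes with the same homologue are argued against as the whole source. Genes that alone match their homologue had medians of -0.28 in root, against -0.46 for the whole list, and -1.26 in leaf. Family members with different homologues may share reads too, which was not tested. More phosphate in the low nitrogen solution is argued against by the recipes, which differ by 0 mM in phosphate. An effect of nitrogen supply on phosphate signalling and an effect of the other ions that differ between the solutions stay open, untested; solutions with the same sulfate and chloride and replicate libraries would be needed to part them.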
